A study of Mus musculus with 19 samples.

How the data were processed

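The series holds 19 samples of splenic natural killer cells, each hybridized to 1 Affymetrix Mouse Gene 1.0 ST array. Per the submitters' processing notes, the deposited intensity values were made with Affymetrix Power Tools and RMA, with no versions or settings given. The deposited table holds 24922 probe sets of intensities on a linear scale, with 0 missing values and 0 values under 1. No raw files, background measures or detection values were used, so signal over background could not be given. Which arrays the authors processed together is not given in the sources used here.

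The deposited intensities lie on 2 scales. The high-intensity set of 7 samples has log2 medians from 7.49 to 7.59, and 20.0% of its probe sets hold a value shared by at least 3 of its samples. The low-intensity set of 12 samples has log2 medians from 5.70 to 5.90 and 0% such probe sets. The median difference between the sets was 1.68 on the log2 scale (SD 0.39 over probe sets). The sets follow the 2 forms of the sample titles except for 1 sample, JAK3 inhibitor 4 µM replicate 1. The fit planned before the data were examined held a term for the title form. A term for the scale set replaced it, which is a departure from the plan, since the title-form term would leave that sample on the wrong scale. Correlations between samples of a group ranged from 0.962 to 0.995 (log2 values as deposited, over 19752 genes). The 2 samples of 4 µM JAK3 inhibitor lie in the low-intensity set.

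Samples were grouped by the titles into untreated (3), IL-2 (4), JAK3 inhibitor at 0.25, 1 and 4 µM (2 each) and JAK1 inhibitor at 0.25 and 1 µM (2 each) and at 0.0625 and 4 µM (1 each). No column was left out. Values were turned into log2. Of the probe sets, 21425 had 1 gene symbol and were used; 1399 had several symbols and 2098 were absent from the annotation table. For 921 genes with several probe sets, the probe set with the highest mean over all samples stood for the gene, which gave 19752 genes. Entrez identifiers matched the reference table for 21347 probe sets, and 0 symbols were updated.

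All 19 samples were fitted with limma 3.58.1 in R 4.3.3 (lmFit with a mean per group and the scale-set term, then eBayes with an intensity trend), with 9 residual and 10.5 prior degrees of freedom. Groups of 1 sample were assumed to vary like the others. P-values were adjusted by Benjamini-Hochberg over the 19752 genes of each comparison, with a threshold of 0.05, and every adjusted p of a gene in the text is from limma. The comparisons were IL-2 against untreated, each inhibitor dose against IL-2, the inhibitors against each other at 0.25, 1 and 4 µM and averaged over 0.25 and 1 µM, and the slope per 4-fold step of dose for each inhibitor. The comparisons of 4 µM with untreated cells were added after the data had been seen.

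Gene lists were written before any value was computed: 24 response lists (667 of 709 entries matched) and 10 cell type marker lists (115 of 130 matched). Entries could be matched through synonyms, and the entry Gpi1 of the glycolysis list was matched to a different gene, Pigq. Each was tested against all other genes with limma's camera at a preset correlation of 0.01 and again with the correlation estimated from the data, and with limma's fry. Adjusted p-values of lists were computed over the lists of a kind within a comparison. Members were also counted after adjustment over the list alone. Besides the lists described in the report, 8 response lists (amino acid transport and ATF4 targets, sterol and fatty acid synthesis, glycolysis, oxidative phosphorylation, apoptosis regulators, JAK-STAT components, immediate early genes and NF-kappaB targets) and 5 marker lists (erythroid, platelet, basophil and mast cell, stroma and endothelium, innate lymphoid types 2 and 3) are described under the other observations.

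The genes named follow a rule set in advance: the genes with the largest rise and fall among those past the threshold, in rank order; up to 4 members with the smallest p of each list described; 11 genes of the IL-2 response (Cish, Socs1, Socs2, Il2ra, Pim1, Myc, Gzmb, Prf1, Bcl2, Ifng and Il7r); and the kinase gene Jak1. Predicted genes could be passed over, and some genes of the rule were not analysed here.

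The percent of the IL-2 response left was the mean over genes of the scale-adjusted log2 values, with untreated at 0% and IL-2 at 100%, for genes changed at least 2-fold by IL-2. Its relation to log2 dose was tested by Pearson's r and Spearman's rho with exact permutations over the samples of an inhibitor. The overlap of calls was set beside n1 × n2 / N, beside simulated groups with no effect, and beside a split of the IL-2 samples. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 and the R package statmod 1.5.0 were used as well.

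The fits were tested on simulated data over 19752 genes. Every group had the same mean per gene apart from added changes, with the fitted scale-set term and independent normal noise of the fitted variance. For IL-2 against untreated they recovered 44 of 67 genes changed 1.5-fold, 66 of 67 changed 2-fold and 66 of 66 changed 4-fold, with 21 false calls. For the inhibitors against each other at 1 µM they recovered 16 of 67, 61 of 67 and 66 of 66, with 14 false calls, and at 4 µM 4 of 67, 39 of 67 and 66 of 66, with 6 false calls. These data hold no correlation between genes and none of the real differences, so such recovery need not hold in the real data. There Ifit1 differed 3.1-fold between the inhibitors at 1 µM and did not pass (adjusted p = 0.364).

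The alternatives tried were quantile normalization first, dim probe sets left out (mean below the median of all probe sets), every probe set counted as itself, log2 of the value plus 16, a robust prior, only the groups compared in the fit, each sample left out in turn, fits within each scale set, no scale-set term, the title-form term, a replicate block, and, for the percent left, other fold thresholds, the median over genes, and genes chosen in 1 scale set and measured in the other. Sample weights were computed but not used, because their estimation did not converge.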

Results

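Natural killer (NK) cells, cytotoxic lymphocytes of the innate immune system, were enriched from the spleens of male C57BL/6 mice by negative selection and profiled on 19 Affymetrix mouse gene arrays. Untreated cells gave 3 samples, and cells cultured with interleukin-2 (IL-2, 250 U/ml) for 8 h gave 4. The other 12 samples received IL-2 together with a kinase inhibitor known by a code name. An inhibitor of JAK3, the kinase bound to the common gamma chain of the IL-2 receptor, was used at 0.25, 1 and 4 µM with 2 samples per dose. An inhibitor of JAK1, the kinase bound to the beta chain, was used at 0.25 and 1 µM with 2 samples per dose and at 0.0625 and 4 µM with 1 sample each. The labels gave 8 h for 2 of the untreated samples and no culture time for the third. They did not say whether samples of a group came from separate mice or cultures, so each p-value measures only the spread between these samples, which may be technical. The intensities fell on 2 scales: 7 samples (the high-intensity set) had log2 medians between 7.49 and 7.59, and 12 samples (the low-intensity set) between 5.70 and 5.90. The untreated, IL-2, 0.25 µM and 1 µM groups spanned both sets, and the 0.0625 and 4 µM samples lay in the low-intensity set. Within either set each inhibitor group at 0.25 or 1 µM held 1 sample. Fits within the high-intensity set had 1 residual degree of freedom and those within the low-intensity set 3. A count of 0 genes within a set therefore does not speak against a difference. The values below come from a fit with a term for the set unless another fit is named. The number of arrays limits the precision of all values below. Values after ± are standard errors of log2 changes unless an SD is named.

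IL-2 changed the expression of 1808 of 19752 genes at 8 h, of which 1296 were higher and 512 lower than in untreated cells (4 samples against 3). The largest rises were in effector genes. Gzmb, which encodes the cytotoxic protease granzyme B, rose by 5.19 ± 0.34 on the log2 scale (adjusted p = 3.49e-09). Cxcl9, a chemokine induced by interferon, rose by 4.52 ± 0.23, and Ifng, the gene of interferon-gamma, by 3.78 ± 0.17. Cxcl10 followed at 3.48 ± 0.27, the costimulatory receptor gene Tnfrsf9 at 3.43 ± 0.19 and the chemokine gene Xcl1 at 3.41 ± 0.20. A predicted gene ranked next was passed over. Genes of cytokine feedback rose as well, among them Socs1 by 3.01 ± 0.14, Cish by 2.10 ± 0.14 and Socs2 by 0.70 ± 0.15. The high-affinity receptor chain gene Il2ra rose by 2.27 ± 0.18, the growth regulator Myc by 2.31 ± 0.19, the survival gene Bcl2 by 2.29 ± 0.17, the perforin gene Prf1 by 2.82 ± 0.23 and the kinase gene Pim1 by 1.08 ± 0.20. The largest falls were in Adgre4 (-3.08 ± 0.19), Clec4a3 (-2.95 ± 0.21), Vcan (-2.95 ± 0.20) and Hpgd (-2.85 ± 0.16), genes expressed by myeloid cells. Il7r, the IL-7 receptor gene, also fell (-1.85 ± 0.17). At least 2-fold changes were seen in 334 of the higher and 120 of the lower genes. The count was 3069 without untreated replicate 2. Within the low-intensity set limma called 962 genes, and within the high-intensity set 0, with 1264 at an unadjusted p under 0.05. After quantile normalization the split was 1429 higher and 1123 lower.

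Genes that respond to interferons rose as a group. All 35 measured type I interferon-stimulated genes rose, with a median log2 change of 1.87 (adjusted p = 7.48e-50 against all other genes, and adjusted p = 0.0372 with an estimated correlation). They included the antiviral genes Zbp1 (3.13 ± 0.27), Usp18 (3.00 ± 0.30) and Mx1 (1.93 ± 0.20). Of 25 interferon-gamma-responsive genes, 22 rose (23 adjusted over the list alone), led by Socs1 and the GTPase gene Iigp1 (3.27 ± 0.16; adjusted p = 0.0232 for the list with an estimated correlation). Of 40 genes of the IL-2/STAT5 response, 29 rose (32 adjusted over the list alone; median 0.99; adjusted p = 0.0232 with an estimated correlation). The cytotoxic granule and death ligand list had 14 of 23 members higher and 2 lower (adjusted p = 0.0232 with an estimated correlation), with Gzmb first and the granule membrane gene Nkg7 next (2.35 ± 0.16). The cytokine and chemokine list had 11 of 21 higher and 1 lower (2 adjusted over the list alone; adjusted p = 0.0141 with an estimated correlation), with Ifng and Xcl1 first, followed by Ccl4 (2.52 ± 0.18). Some of these lists share members, among them Socs1 and Gzmb, which are also on the IL-2/STAT5 list, so their results are not independent. In the same samples 8 of 15 macrophage and monocyte markers fell and 1 rose, as described below.

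Genes of growth and protein synthesis rose to differing extents. Of 45 genes of ribosome biogenesis and the nucleolus, 42 rose (43 adjusted over the list alone), with a median of 0.89 and Rrp1b (1.53 ± 0.15) and Dkc1 (1.52 ± 0.17) first. With an estimated correlation the list had adjusted p = 0.0523. Of 24 genes of polyamine, nucleotide and one-carbon metabolism, 20 rose (21 adjusted over the list alone), led by the spermidine synthase gene Srm (2.12 ± 0.17), with adjusted p = 0.0523 with an estimated correlation. Cytosolic chaperones rose in 13 of 20 members, led by Hspd1 (1.16 ± 0.14), with adjusted p = 0.0523 with an estimated correlation. Endoplasmic reticulum chaperones rose in 13 of 23, led by Creld2 (1.34 ± 0.20) and Hspa5 (1.01 ± 0.15), with adjusted p = 0.0647 with an estimated correlation. Each list gave 15 members when adjusted over the list alone. Translation factors rose in 10 of 19 members (13 adjusted over the list alone; Eef1e1 1.00 ± 0.14; adjusted p = 0.12 with an estimated correlation) and proteasome subunits in 11 of 28 (19 adjusted over the list alone; Psmd6 0.74 ± 0.15; adjusted p = 0.162 with an estimated correlation). Among G1/S cell cycle genes 9 of 37 rose (17 adjusted over the list alone), led by the cyclin gene Ccnd2 (2.72 ± 0.19), with adjusted p = 0.245 with an estimated correlation. For G2/M genes 0 of 30 rose and 1 fell, with a median of -0.08 and adjusted p = 0.0891.

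NK cell receptor genes moved in both directions: 15 of 31 rose and 4 fell (17 and 5 adjusted over the list alone; adjusted p = 0.184 with an estimated correlation). Cd7 fell (-1.90 ± 0.14) and the activating receptor gene Ncr1 rose (2.2 ± 0.18). Of 21 NK cell transcription factors, 9 rose and 1 fell, with Id2 (1.36 ± 0.14) and Zbtb32 (1.21 ± 0.14) first and adjusted p = 0.162 with an estimated correlation. Among 31 FOXO targets and quiescence genes 9 fell and 2 rose (14 and 3 adjusted over the list alone; adjusted p = 0.287 with an estimated correlation). Il7r and the chemokine receptor gene Cxcr4 (-1.04 ± 0.11) fell, while Gimap4 rose (1.21 ± 0.14). Markers of other cell types fell in the same samples. Of 15 macrophage and monocyte markers 8 fell and 1 rose, with a median of -0.62, and the lysozyme gene Lyz2 (-1.87 ± 0.14), Cd14 (-1.95 ± 0.18) and Csf1r (-1.93 ± 0.18) were first (adjusted p = 0.0118 with an estimated correlation). Of 15 neutrophil markers 9 fell (11 adjusted over the list alone; Mmp8 -2.50 ± 0.23; adjusted p = 0.0568 with an estimated correlation). Of 15 B cell markers 5 fell (8 adjusted over the list alone; Fcer2a -0.99 ± 0.15; adjusted p = 0.0731 with an estimated correlation). Of 13 dendritic cell markers 3 fell and 2 rose (adjusted p = 0.0731 with an estimated correlation), with Cd209a at -2.10 ± 0.12. The T cell list had a median of 0.05 and adjusted p = 0.517, and its median was negative after quantile normalization.

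At the lowest dose of the JAK3 inhibitor, 0.25 µM, effector genes fell against IL-2 alone (2 samples against 4). The cytotoxic granule and death ligand list had 9 of 23 members lower and 2 higher (10 and 2 adjusted over the list alone; adjusted p = 0.0247 with an estimated correlation). The cytokine and chemokine list had 10 of 21 lower and 1 higher (11 and 2 adjusted over the list alone; adjusted p = 0.0098 with an estimated correlation). Gzmb fell (-4.35 ± 0.39), as did Ifng (-3.77 ± 0.19; adjusted p = 4.26e-10), Sh2d1b2 (-2.98 ± 0.25), an adaptor gene of NK cells, and Xcl1 (-2.98 ± 0.23). Socs1 (-2.35 ± 0.15), Cish (-1.97 ± 0.16), Il2ra (-1.96 ± 0.20), Myc (-1.83 ± 0.21), Prf1 (-2.48 ± 0.26) and Bcl2 (-1.88 ± 0.19) fell too, and Il7r rose (1.90 ± 0.19). Socs2 gave -0.40 ± 0.17 and did not pass the test (adjusted p = 0.294). Of the IL-2/STAT5 list 22 of 40 members fell (24 adjusted over the list alone; adjusted p = 0.0265 with an estimated correlation), and of the ribosome biogenesis list 29 of 45 fell (40 adjusted over the list alone; adjusted p = 0.0336 with an estimated correlation). Only 2 of 35 type I interferon-stimulated genes, Mx1 (-1.04 ± 0.22) and Zbp1 (-1.24 ± 0.31), fell (11 adjusted over the list alone). The median of that list was -0.54, with adjusted p = 0.183 with an estimated correlation. The largest rises were in Clec4a3 (2.93 ± 0.24), Clec4a1 (2.92 ± 0.19) and Adgre4 (2.86 ± 0.22), and 8 of 15 macrophage and monocyte markers rose (adjusted p = 0.00216 with an estimated correlation). In all 987 genes passed, 541 higher and 446 lower. The count was 309 without replicate 1 of this dose and 322 without replicate 2. The call of Mx1 ended without either (adjusted p = 0.12 and 0.0965), and that of Zbp1 without replicate 1 (adjusted p = 0.507) or IL-2 replicate 3 or 4 (adjusted p = 0.0759 and 0.0591). The count was 113 within the low-intensity set and 0 within the high-intensity set, where 939 genes had an unadjusted p under 0.05.

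At 1 and 4 µM of the JAK3 inhibitor interferon-stimulated genes fell as well. At 1 µM 33 of 35 fell (35 adjusted over the list alone), with a median of -1.57 and adjusted p = 0.0358 with an estimated correlation. Zbp1 (-2.58 ± 0.31) and Usp18 (-2.57 ± 0.34) were first. At 4 µM all 35 fell, with a median of -2.03, Ifit1 (-2.85 ± 0.26) and Usp18 (-3.76 ± 0.35) first, and adjusted p = 0.0484 with an estimated correlation. Gzmb stood at -5.15 ± 0.39 and -4.99 ± 0.41 at 1 and 4 µM against IL-2 alone, Ifng at -3.79 ± 0.19 and -4.05 ± 0.20, Cxcl9 at -3.68 ± 0.26 and -4.96 ± 0.27, Cish at -1.85 ± 0.16 and -2.20 ± 0.16, and Il2ra at -2.31 ± 0.20 and -2.93 ± 0.21, and each of these falls passed the test. Adgre4 led the rises at both doses (3.44 ± 0.22 and 3.29 ± 0.23), followed by Clec4a3 (3.27 ± 0.24) at 1 µM and Vcan (2.94 ± 0.24) at 4 µM. The IL-2/STAT5 list had 26 and 27 of 40 members lower (27 and 30 adjusted over the list alone), with adjusted p = 0.0204 and adjusted p = 0.0484 with an estimated correlation. Ribosome biogenesis genes fell in 34 and 35 of 45 members (44 and 40 adjusted over the list alone), with adjusted p = 0.0364 and adjusted p = 0.095 with an estimated correlation. Macrophage and monocyte markers rose in 8 and 7 of 15, with 0 and 1 lower.

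In total 1293 genes passed at 1 µM of the JAK3 inhibitor (565 higher, 728 lower; 2 samples against 4) and 1483 at 4 µM (594 higher, 889 lower; 2 against 4). At 4 µM the direction with more genes depended on which of the 2 samples was left out. These samples differed most in the G2/M list, with mean log2 values of 5.591 and 6.792 (replicates 1 and 2). The 1 µM count was 563 without its replicate 1 and 468 without its replicate 2. After quantile normalization the split was 1058 higher and 1004 lower at 1 µM and 1307 higher and 1191 lower at 4 µM. Within the low-intensity set the counts were 261 and 638. The high-intensity set held 1 of the 1 µM samples and called 0 genes there, with 1247 at an unadjusted p under 0.05. By the slope over the 3 doses of the JAK3 inhibitor, 27 genes fell and 3 rose per 4-fold step in dose. This slope compares 4 with 0.25 µM and gives no weight to the 1 µM samples. A change at every step was not tested. Ifit3 fell by 1.39 ± 0.21 per step, Usp18 by 1.33 ± 0.20 and Rtp4 by 1.29 ± 0.18, all interferon-induced, and Ubxn2a rose by 0.66 ± 0.12. Of the type I interferon-stimulated list 14 of 35 fell with dose (34 adjusted over the list alone; adjusted p = 0.14 with an estimated correlation). Neither Gzmb (-0.32 ± 0.23) nor Ifng (-0.14 ± 0.11) changed with dose by this test (adjusted p = 0.729 and adjusted p = 0.773). The 30 genes became 0 without replicate 2 of 0.25 µM and 171 without replicate 2 of 4 µM. The calls of Ifit3, Usp18, Rtp4 and Ubxn2a ended without replicate 2 of 0.25 µM (adjusted p = 0.65, 1, 0.498 and 1), and that of Ubxn2a also without replicate 1 of 4 µM (adjusted p = 0.157). The count of 30 was 29 within the low-intensity set.

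The JAK1 inhibitor at 0.0625 µM was measured in 1 sample, which was assumed to vary like the other groups. The number of genes called at this dose was far larger with only the compared groups fitted or with a replicate block. Against IL-2 alone (4 samples) 3 genes were lower: the interferon-inducible Iigp1 (-1.90 ± 0.24), the purine salvage gene Pnp (-2.10 ± 0.32) and the translation factor gene Eif2s2 (-1.39 ± 0.23). The microRNA gene Mir465 was higher (1.84 ± 0.18). Gzmb gave -0.34 ± 0.51 and Ifng -0.67 ± 0.25, with adjusted p = 0.822 and adjusted p = 0.334. The count of 4 became 17 without IL-2 replicate 1 and 2 without IL-2 replicate 3. The call of Eif2s2 ended without IL-2 replicate 2, 3 or 4 (adjusted p = 0.0801, 0.186 and 0.125) and that of Pnp without IL-2 replicate 3 (adjusted p = 0.0791). The count was 9 within the low-intensity set. At 0.25 µM (2 samples against 4) the pattern was led by interferon genes. Iigp1 (-2.58 ± 0.18; adjusted p = 1.62e-07), Slfn5 (-2.56 ± 0.34) and Ifit3 (-2.49 ± 0.35) fell most, and 30 of 35 type I interferon-stimulated genes fell (34 adjusted over the list alone), with a median of -1.35 and adjusted p = 0.0545 with an estimated correlation. Cish (-1.04 ± 0.16), Socs1 (-1.27 ± 0.15), Il2ra (-1.32 ± 0.20), Myc (-0.95 ± 0.21) and Ifng (-1.0 ± 0.19) fell too. Gzmb gave -1.36 ± 0.39 (adjusted p = 0.0776) and Bcl2 -0.38 ± 0.19 (adjusted p = 0.432). Of the IL-2/STAT5 list 11 of 40 fell (20 adjusted over the list alone; adjusted p = 0.0646 with an estimated correlation), and of the ribosome biogenesis list 16 of 45 (38 adjusted over the list alone; adjusted p = 0.0646 with an estimated correlation). The myeloid genes Clec4a3 (2.28 ± 0.24) and Clec4a1 (1.97 ± 0.19) rose most, with 2 of 15 macrophage and monocyte markers higher (adjusted p = 0.0636 for the list).

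At 0.25 µM of the JAK1 inhibitor 445 genes passed, 144 higher and 301 lower. This count was 97 without replicate 1 of the dose and 32 without replicate 2. It was 236, 211 and 215 without IL-2 replicates 2, 3 and 4, and 723 without IL-2 replicate 1. The calls of Cish, Il2ra, Myc, Ifng and Ifit3 ended without replicate 2 of the dose (adjusted p = 0.106, 0.144, 0.168, 0.375 and 0.0967). That of Myc also ended without replicate 1 (adjusted p = 0.397) or IL-2 replicate 2, 3 or 4 (adjusted p = 0.0585, 0.0763 and 0.0705), and Gzmb passed without IL-2 replicate 1 (adjusted p = 0.05). The split was 543 higher and 584 lower after quantile normalization. Within the low-intensity set 53 genes passed, and within the high-intensity set 0, with 787 at an unadjusted p under 0.05.

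At 1 µM of the JAK1 inhibitor (2 samples against 4) Cxcl10 (-4.15 ± 0.30), Cxcl9 (-4.13 ± 0.26), Ifit3 (-3.70 ± 0.35) and Gzmb (-3.67 ± 0.39; adjusted p = 2.87e-06) fell most. At 4 µM (1 sample against 4) Cxcl9 (-5.24 ± 0.34), Gzmb (-4.88 ± 0.51) and Ifit3 (-4.14 ± 0.46) led. All 35 type I interferon-stimulated genes fell at both doses, with medians of -1.81 and -2.42 and adjusted p = 0.0111 and adjusted p = 0.0392 with an estimated correlation. Ifng fell (-3.02 ± 0.19 and -3.94 ± 0.25), as did Cish (-1.69 ± 0.16 and -2.43 ± 0.21), Socs1 (-2.46 ± 0.15 and -2.68 ± 0.20), Il2ra (-2.02 ± 0.20 and -2.09 ± 0.27) and Bcl2 (-1.61 ± 0.19 and -2.48 ± 0.25). The IL-2/STAT5 list had 20 of 40 members lower at each dose (25 and 27 adjusted over the list alone), with adjusted p = 0.0188 and adjusted p = 0.0568 with an estimated correlation. Il7r rose (1.62 ± 0.19 and 1.87 ± 0.25). Adgre4 (3.01 ± 0.22) and Clec4a3 (3.00 ± 0.24) rose most at 1 µM, and Clec4a3 (2.99 ± 0.32) and Tlr8 (2.81 ± 0.28) at 4 µM. Macrophage and monocyte markers rose in 7 and 6 of 15, with 0 and 1 lower. At 1 µM 1019 genes passed (562 higher, 457 lower), and 256 without replicate 2 of that dose. At 4 µM 745 passed (225 higher, 520 lower), and 493 without IL-2 replicate 3. After quantile normalization the 4 µM split was 630 higher and 681 lower, and the median change over all genes moved by 0.108, from -0.10 to 0.01. Within the low-intensity set 257 and 315 genes passed, and within the high-intensity set 0 at 1 µM, with 994 at an unadjusted p under 0.05.

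By the slope per 4-fold step in the dose of the JAK1 inhibitor (6 samples over 4 doses) 388 genes fell and 161 rose. Cxcl9 (-1.69 ± 0.13 per step), Gzmb (-1.60 ± 0.20) and the interferon-induced Oasl2 (-1.24 ± 0.14) fell most, and Ifng (-1.18 ± 0.10), Socs1 (-0.70 ± 0.08), Cish (-0.61 ± 0.08) and Bcl2 (-0.89 ± 0.10) fell. Adgre4 (0.84 ± 0.11), Clec4n (0.82 ± 0.10) and Hpgd (0.78 ± 0.09) rose most, and Il7r rose (0.61 ± 0.09). Type I interferon-stimulated genes fell in 25 of 35 (32 adjusted over the list alone; adjusted p = 0.233 with an estimated correlation) and IL-2/STAT5 genes in 16 of 40 (18 adjusted over the list alone; adjusted p = 0.413 with an estimated correlation). Macrophage and monocyte markers rose in 8 of 15 (adjusted p = 0.03 with an estimated correlation). The 549 genes became 312 without replicate 1 of 0.25 µM. The split after quantile normalization was 464 higher and 447 lower, and 103 genes passed within the low-intensity set.

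**Figure D1:**
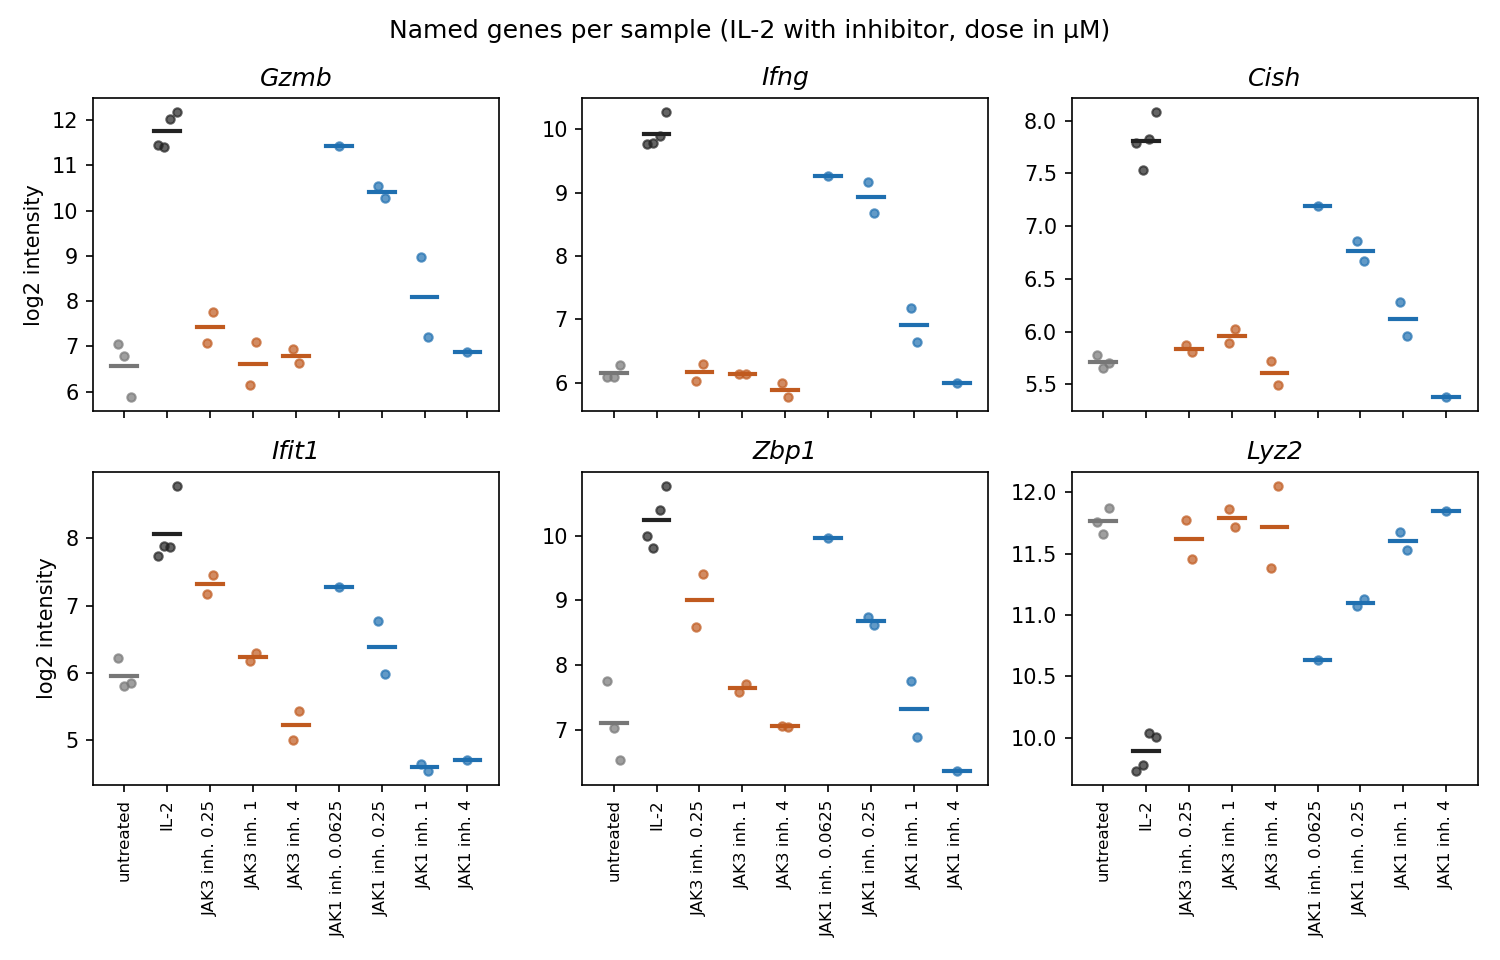
Expression of 6 named genes in each of the 19 samples (points; log2 intensity after removal of the difference between the scale sets) with the mean of each group (bars), for untreated cells, IL-2 alone and IL-2 with either inhibitor at rising dose in µM. Gzmb and Ifng sat higher at 0.25 µM of the JAK1 inhibitor (means 10.41 and 8.93) than at 0.25 µM of the JAK3 inhibitor (7.42 and 6.16), while Ifit1 sat lower (6.38 against 7.32), and Lyz2 was lowest with IL-2 alone (9.89).

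The genes that the inhibitors changed were largely those that IL-2 had changed, in the opposite direction. Of the 1296 genes that IL-2 raised, the JAK3 inhibitor lowered 433 at 0.25 µM, 706 at 1 µM and 725 at 4 µM, and the JAK1 inhibitor lowered 262 at 0.25 µM, 451 at 1 µM and 479 at 4 µM. Lists drawn independently would share 29.3, 47.8 and 58.3 genes for the JAK3 inhibitor and 19.7, 30.0 and 34.1 for the JAK1 inhibitor. Of the 512 genes that IL-2 lowered, the JAK3 inhibitor raised 388, 417 and 378 (14.0, 14.6 and 15.4 for independent lists), and the JAK1 inhibitor raised 111 and 400 at 0.25 and 1 µM and 37.7% of the 512 at 4 µM (3.73, 14.6 and 5.83 genes). Both comparisons of each pair used the same IL-2 samples, which alone can create overlap. Simulated groups with no effect against those samples shared 0 genes, a value that leaves out the real effects and so does not measure this overlap. With the IL-2 samples split so that each comparison used its own pair, the raised genes still shared 282, 444 and 490 for the JAK3 inhibitor and 156, 320 and 352 for the JAK1 inhibitor, and the lowered genes 213, 241 and 237 and 53, 219 and 119.

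The share of the IL-2 response left at each dose was read from the 334 genes that IL-2 induced at least 2-fold, with IL-2 alone set to 100% ± 12 (SD, n = 4) and untreated cells to 0% ± 17.9 (SD, n = 3). With the JAK3 inhibitor 33.6% ± 8.36 (SD, n = 2) was left at 0.25 µM, 11.0% ± 4.31 (SD, n = 2) at 1 µM and 0.139% ± 13.3 (SD, n = 2) at 4 µM. With the JAK1 inhibitor 71.6% (1 sample) was left at 0.0625 µM, 48.2% ± 1.22 (SD, n = 2) at 0.25 µM, 17.9% ± 11.3 (SD, n = 2) at 1 µM and -5.73% (1 sample) at 4 µM. The 120 genes that IL-2 repressed at least 2-fold were back to the untreated level with the JAK3 inhibitor at 0.25 µM, with 0.206% ± 2.2 (SD, n = 2) left, then -6.83% ± 6.64 (SD, n = 2) and 2.22% ± 10.7 (SD, n = 2). With the JAK1 inhibitor they kept 78.4% (1 sample), 48.5% ± 4.17 (SD, n = 2), 1.56% ± 2.63 (SD, n = 2) and 8.48% (1 sample) from the lowest to the highest dose. The repressed genes with the largest falls are expressed by myeloid cells. Their percent left may thus follow the share of such cells in a sample as well as a response of NK cells, which was not tested. With genes chosen in the low- and measured in the high-intensity set, the induced genes kept 15.7 and -11.7% at 0.25 and 1 µM of the JAK3 inhibitor. There 0% was set by the 1 untreated sample of the measured set, replicate 2, which stood at 16.9% in the main measure. The shift thus need not come from the choice of genes. With the same choice the repressed genes kept 8.31 and 3.18% at 0.25 and 1 µM of the JAK3 inhibitor and 12.9% at 1 µM of the JAK1 inhibitor. The opposite choice left -8.58 and -22.5% of the repressed genes' response at 0.25 and 1 µM of the JAK3 inhibitor, and -9.59 and 0.837% at 1 and 4 µM of the JAK1 inhibitor. Without untreated replicate 2 the percent left of the induced genes was 23.7 and 12.8 at 1 and 4 µM of the JAK3 inhibitor and 33.0 and 6.06 at 1 and 4 µM of the JAK1 inhibitor, and without untreated replicate 3 it was 2.17, -10.9, 7.85 and -17.4. At 1 µM of the JAK1 inhibitor it was 8.88 and 27.6 without replicates 1 and 2 of that dose. For the repressed genes, leaving out untreated replicate 2, 3 or 4 gave 6.17, 4.67 and 3.93 at 0.25 µM of the JAK3 inhibitor and 9.32, 5.8 and 4.84 at 1 µM of the JAK1 inhibitor, and at 4 µM of the latter 15.4 without untreated replicate 3. At 1 µM of the JAK3 inhibitor the repressed genes ranged from -12.1 without replicate 1 of that dose to -0.766 without its replicate 2. At 4 µM they ranged from -5.24 without replicate 1 of that dose to 9.11 without its replicate 2.

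For the induced genes the percent left fell with log2 dose of the JAK1 inhibitor over 6 samples (r = -0.982, two-sided exact permutation p = 0.0111, adjusted 0.0444 over the 4 relations computed; rho = -0.971, exact p = 0.0111, adjusted 0.0444), and r was -0.936 without the samples of the lowest and highest dose and -0.989 among the 4 samples of the low-intensity set. With the JAK3 inhibitor r was -0.884 (exact p = 0.0444, adjusted 0.0592; rho = -0.837, exact p = 0.0667, adjusted 0.104), which did not pass after adjustment. It was -0.923 without the 4 µM samples, -0.612 without the 0.25 µM samples and -0.913 among the 4 samples of the low-intensity set. For the repressed genes r was -0.904 with the JAK1 inhibitor (exact p = 0.0333, adjusted 0.0592; rho = -0.794, exact p = 0.0778, adjusted 0.104), -0.995 without the lowest and highest dose and -0.912 within the low-intensity set, and 0.126 with the JAK3 inhibitor (exact p = 0.844, adjusted 0.844; rho = -0.120, exact p = 0.844, adjusted 0.844), where all 3 doses lay near 0%. For the JAK3 inhibitor that r was -0.708 without the 4 µM samples, 0.582 without the 0.25 µM samples, 0.150 within the low-intensity set and -0.0781 without untreated replicate 2. The high-intensity set held 2 samples of each inhibitor, too few for a correlation.

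**Figure D2:**
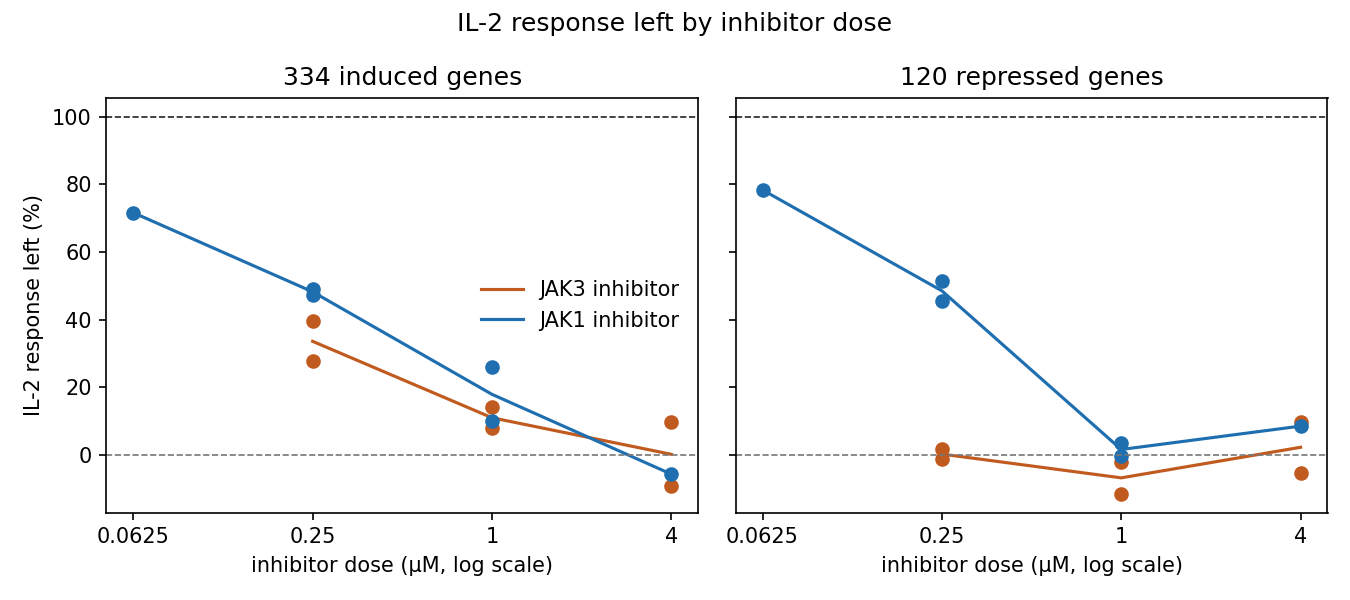
Percent of the IL-2 response left (y axis) against inhibitor dose in µM (x axis, log scale) for the 334 induced genes (left) and the 120 repressed genes (right); points are samples, lines join group means, and the dashed lines mark IL-2 alone (100%) and untreated cells (0%). At 0.25 µM the induced genes kept 33.6% with the JAK3 inhibitor and 48.2% with the JAK1 inhibitor, and the repressed genes kept 0.206% and 48.5%. The repressed genes include markers of myeloid cells, whose share in the samples was not measured.

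At 0.25 µM the inhibitors differed directly in 89 genes (2 samples against 2), 47 higher and 42 lower with the JAK1 inhibitor. After quantile normalization 146 were higher and 127 lower, and with only the compared groups fitted 1114 differed. That fit, and those of the same kind at 1 and 4 µM, had 1 residual degree of freedom, so their counts rest on a less certain spread. Gzmb was higher with the JAK1 inhibitor by 2.99 ± 0.45 (adjusted p = 0.00252), Ifng by 2.76 ± 0.22 (adjusted p = 1.56e-06) and the NK receptor gene Klrb1a by 2.65 ± 0.34. Prf1 (1.61 ± 0.30), Bcl2 (1.49 ± 0.22), Socs1 (1.08 ± 0.18) and Cish (0.93 ± 0.18) were higher too. Il2ra differed by 0.64 ± 0.24 and Myc by 0.88 ± 0.25, which did not pass (adjusted p = 0.479 and adjusted p = 0.179). Slfn5 (-1.94 ± 0.40), Snord37 (-1.43 ± 0.30) and Nfam1 (-1.39 ± 0.23) were lowest relative to the JAK3 inhibitor. Of the IL-2/STAT5 list 9 of 40 members were higher (13 adjusted over the list alone; adjusted p = 0.223 with an estimated correlation). Of the type I interferon-stimulated list 0 of 35 passed singly by limma (20 lower adjusted over the list alone), with a median of -0.77 and adjusted p = 0.223 with an estimated correlation. Macrophage and monocyte markers were lower with the JAK1 inhibitor in 7 of 15 members (9 adjusted over the list alone; adjusted p = 0.00137 with an estimated correlation). Leaving out any 1 of the 4 samples left 5 to 23 genes: 5 and 19 without replicates 1 and 2 of the JAK3 inhibitor, and 20 and 23 without those of the JAK1 inhibitor. Ifng passed each time. Cish, Socs1, Slfn5 and Snord37 did not pass in any of these 4 fits (lowest adjusted p = 0.126, 0.0583, 0.0886 and 0.319). Gzmb lost its call without replicate 1 of either inhibitor (adjusted p = 0.152 and 0.0682) and Klrb1a without replicate 1 of the JAK3 inhibitor (adjusted p = 0.0601). Without replicate 1 of the JAK3 inhibitor Bcl2, Prf1 and Nfam1 also lost theirs (adjusted p = 0.129, 0.137 and 0.222). So did Prf1 and Nfam1 without its replicate 2 (adjusted p = 0.417 and 0.0816), Nfam1 without replicate 1 of the JAK1 inhibitor (adjusted p = 0.207), and Bcl2 and Prf1 without its replicate 2 (adjusted p = 0.0647 and 0.446). Within the scale sets limma called 0 genes, with 727 (high-intensity) and 862 (low-intensity) at an unadjusted p under 0.05.

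At 1 µM limma called 0 genes different between the inhibitors (2 samples against 2), with 167 at an unadjusted p under 0.05, and at 4 µM also 0 (1 sample against 2), with 532. The 95% intervals of the difference at 1 µM, JAK1 inhibitor minus JAK3 inhibitor, were -0.22 to 0.54 for Cish, -0.13 to 0.62 for Socs1, -0.21 to 0.78 for Il2ra, 0.54 to 2.41 for Gzmb and 0.32 to 1.23 for Ifng. At 4 µM they were -0.69 to 0.24 for Cish, -1.04 to 1.25 for Gzmb, -0.45 to 0.67 for Ifng and 0.24 to 1.45 for Il2ra. The signs of 4 estimates turned on leaving out 1 sample: Cish at 1 µM without replicate 1 of the JAK1 inhibitor (-0.026), and at 4 µM Gzmb and Ifng without replicate 1 of the JAK3 inhibitor (-0.055 and -6.3e-04), beside Jak1 without its replicate 2 (0.029). Leaving out replicate 2 of 1 µM JAK1 inhibitor gave 2 genes at 1 µM, and leaving out replicate 2 of 4 µM JAK3 inhibitor gave 27 at 4 µM. With only the compared groups fitted the counts were 84 and 1. Within the low-intensity set the counts were 0 and 0, with 1062 and 335 at an unadjusted p under 0.05, and within the high-intensity set 0 at 1 µM, with 637. At 1 µM the type I interferon-stimulated list was lower with the JAK1 inhibitor with a median of -0.45 (adjusted p = 6.20e-41, and adjusted p = 0.313 with an estimated correlation), with 0 of 35 members past the test and 8 adjusted over the list alone. At 4 µM its median was -0.42, with 0 of 35 past either adjustment and adjusted p = 0.971 with an estimated correlation.

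Averaged over 0.25 and 1 µM (4 samples against 4) 42 genes differed, 30 higher and 12 lower with the JAK1 inhibitor. Higher were Gzmb (2.23 ± 0.32), Klrb1a (2.03 ± 0.24), Ifng (1.77 ± 0.15; adjusted p = 8.72e-06), Xcl1 (1.67 ± 0.19) and the receptor gene Ncr1 (1.5 ± 0.17). Lower were Slfn5 (-1.68 ± 0.28), Ifit1 (-1.28 ± 0.20), the interferon regulator Irf7 (-1.25 ± 0.24) and Rtp4 (-1.22 ± 0.24). Type I interferon-stimulated genes were lower in 4 of 35 members (21 adjusted over the list alone), with a median of -0.58 and adjusted p = 0.0491 with an estimated correlation. IL-2/STAT5 genes were higher in 7 of 40 (13 adjusted over the list alone; adjusted p = 0.132 with an estimated correlation). NK cell receptor genes were higher in 5 of 31 (15 adjusted over the list alone; adjusted p = 0.0491 with an estimated correlation), led by Ncr1 and Klrb1f (0.99 ± 0.14). The macrophage and monocyte list was lower, with a median of -0.45, adjusted p = 0.000726 with an estimated correlation and 0 of 15 members past the test (9 adjusted over the list alone). Leaving out any 1 of the 8 samples left 17 to 29 genes. At 0.25 µM these were 21 and 17 without replicates 1 and 2 of the JAK3 inhibitor and 17 without replicate 2 of the JAK1 inhibitor, and at 1 µM 18 and 19 without those of the JAK3 inhibitor and 20 without replicate 1 of the JAK1 inhibitor. The 5 genes named as higher passed in all 8 fits. Slfn5 and Ifit1 lost their calls without replicate 2 of any of the 4 groups, with adjusted p up to 0.13 and 0.0829, both at 0.25 µM. Irf7 and Rtp4 lost theirs in those 4 fits and without replicate 1 of 1 µM JAK3 inhibitor, with adjusted p up to 0.297 and 0.402. Irf7 also lost it without replicate 1 of 0.25 µM JAK1 inhibitor (adjusted p = 0.11) and Rtp4 without replicate 1 of 1 µM JAK1 inhibitor (adjusted p = 0.122). After quantile normalization the split was 72 higher and 53 lower. Within the low- and high-intensity sets limma called 0 genes, with 694 and 446 at an unadjusted p under 0.05.

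**Figure D3:**
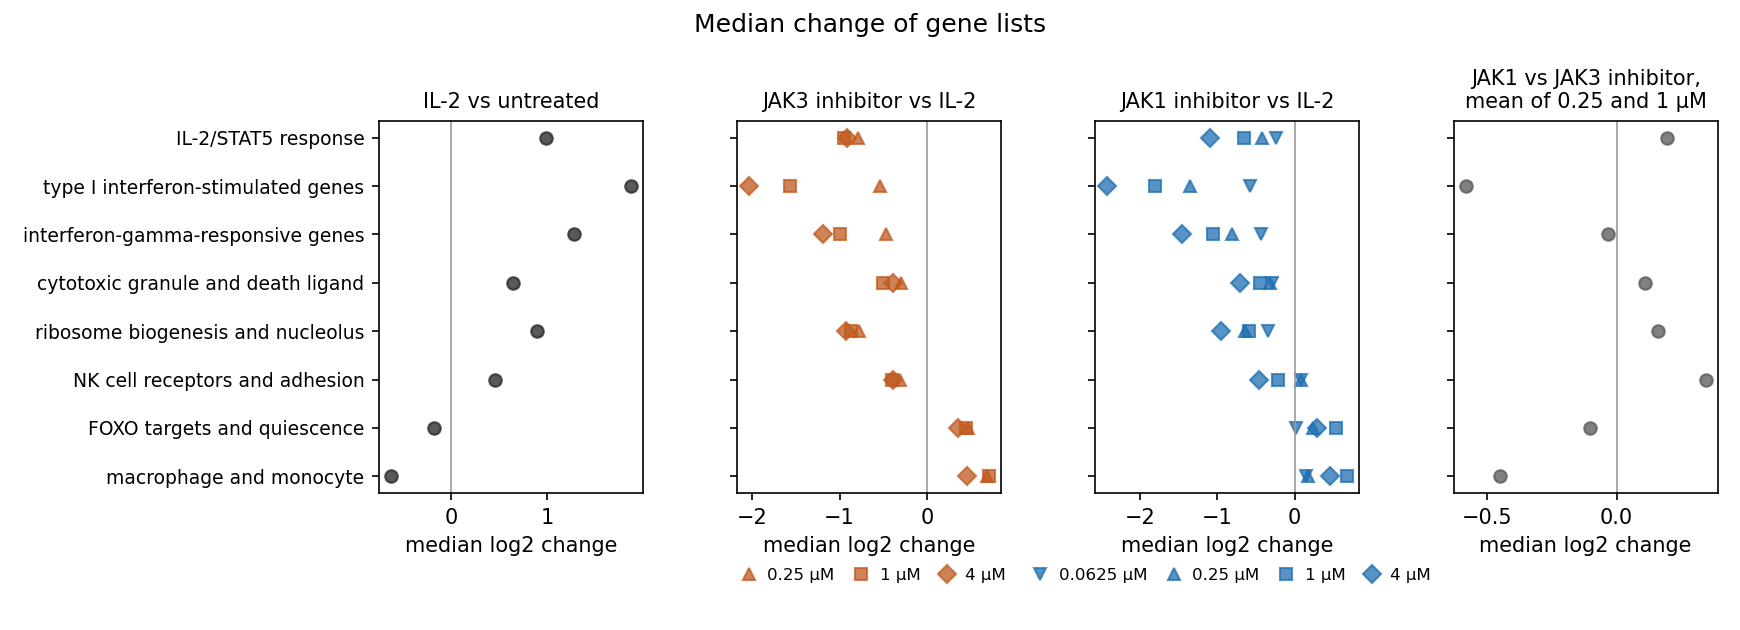
Median log2 change (x axis) of 8 gene lists (y axis) for IL-2 against untreated cells, for each inhibitor dose against IL-2 alone, and for the averaged difference between the inhibitors; each point is the median over a list's measured genes. The type I interferon-stimulated list stood at 1.87 with IL-2, at -0.54 with 0.25 µM of the JAK3 inhibitor and at -1.35 with 0.25 µM of the JAK1 inhibitor.

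The gene of the targeted kinase Jak1 had a mean log2 intensity of 10.61 in untreated cells and 10.35 with IL-2, a change of -0.26 ± 0.12 that did not pass the test (adjusted p = 0.238, and 0.0239 without untreated replicate 3). Its mean was 10.72, 10.76 and 10.95 with rising doses of the JAK3 inhibitor and 10.29, 10.57, 10.79 and 10.84 with rising doses of the JAK1 inhibitor. Only the 4 µM JAK3 group passed against IL-2 alone (0.61 ± 0.14; adjusted p = 0.00899, and 0.111 without replicate 2 of that dose), and Jak1 did not differ between the inhibitors at 4 µM by the test (-0.52 to 0.28, 95% interval). In a comparison added after seeing the data, limma called 0 genes between untreated cells and IL-2 with 4 µM of the JAK3 inhibitor (2 samples against 3; 1714 at an unadjusted p under 0.05) or the JAK1 inhibitor (1 against 3; 1270). For the JAK3 inhibitor this became 49 and 15 without replicates 2 and 1 of that dose and 1 without untreated replicate 2, and for the JAK1 inhibitor 1 and 2 without untreated replicates 2 and 3. It was 39 for the JAK3 inhibitor with a term for the title form after quantile normalization, and 78 for the JAK1 inhibitor with only the compared groups fitted. The fit of only the compared groups had 1 residual degree of freedom. With a replicate block after quantile normalization the count for the JAK3 inhibitor was 4419. Whether replicate numbers pair the samples could not be told. The type I interferon-stimulated list lay below the untreated level with the JAK1 inhibitor, with a median of -0.61, 0 of 35 members past the test, 10 lower adjusted over the list alone and adjusted p = 0.702 with an estimated correlation. With the JAK3 inhibitor its median was -0.22 (adjusted p = 0.987 with an estimated correlation).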

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

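The tests of the myeloid markers, of the 2 lists compared between the inhibitors, of the lists at 0.0625 µM and the fit without a term for dose were chosen only after the results had been seen.

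The IL-2 samples were not alike. IL-2 replicate 1 lay below the other 3 by a wide gap in 6 of 48 measures tested within the IL-2 group: mean log2 values of 8.488 for endoplasmic reticulum chaperones, 8.068 for IL-2/STAT5 genes, 7.838 for NF-kappaB targets and 7.89 for NK cell transcription factors, and log2 levels of 6.969 for Socs2 and 9.493 for Myc. The gap was above the 95% limit of Dixon's test for 4 samples. Chance alone passes that limit in about 1 of 20 groups, and these measures are not independent of each other. The percent of the IL-2 response over induced genes was 83.7% in this sample and 99.5, 105 and 112% in the others. No cause was tested. Of the 35 splits of the 7 IL-2 and untreated samples, 1, the real one, gave 1808 genes, and the highest other gave 1356. A share of 1 of 35 is the smallest these splits can give, so chance is unlikely but not excluded. The split with 1356 genes set IL-2 replicates 2, 3 and 4 against the untreated samples with IL-2 replicate 1.

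The inhibitors differed in 89 genes at 0.25 µM and in 42 averaged over 0.25 and 1 µM by a test of the difference itself. Type I interferon-stimulated genes tended to be lower with the JAK1 inhibitor, with 0 and 4 of 35 members past the test at 0.25 µM and averaged (adjusted p = 0.223 and adjusted p = 0.0491 for the list with limma's camera and an estimated correlation). IL-2/STAT5 genes tended to be higher, with 9 and 7 of 40 members past the test (adjusted p = 0.223 and adjusted p = 0.132). Over both doses (4 samples against 4) the JAK1 inhibitor left 43.9% ± 17.7 (SD) of the IL-2/STAT5 list's response and the JAK3 inhibitor 16.3% ± 8.96 (SD). Of the interferon list's response they left 4.56% ± 24.6 (SD) and 41.8% ± 33.2 (SD), a difference of -37.2 (95% interval -67 to -7.49). These SDs include the difference between the doses. At 0.25 and 1 µM (2 samples each) 58.2 and 29.6% of the IL-2/STAT5 response was left with the JAK1 inhibitor and 23.3 and 9.34% with the JAK3 inhibitor. For the interferon list it was 23.7 and -14.5% with the JAK1 inhibitor and 68.4 and 15.1% with the JAK3 inhibitor. The gap between the lists differed by -64.8 between the inhibitors, and lay at -55.5, -104, -51.3 and -48.6 within each dose and scale set. Macrophage and monocyte markers were lower with the JAK1 inhibitor as well, with 7 and 0 of 15 members past the test at 0.25 µM and averaged (adjusted p = 0.00137 and adjusted p = 0.000726 with an estimated correlation). The differences in percent left, for either list and for the gap, each had an exact permutation p of 0.0556 (adjusted 0.0556), the smallest that 36 arrangements within dose can give. Arrangements without regard to dose, computed first, gave exact permutation p = 0.0571 for the IL-2/STAT5 list, 0.143 for the interferon list and 0.0286 for the gap. The intervals come from a linear model with terms for dose and scale set, added after these p-values had been seen.

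A stronger overall block by the JAK1 inhibitor would lower what is left of both lists. In these samples the IL-2/STAT5 difference of 27.5 has the opposite sign (95% interval 11.5 to 43.5). That difference is a part of the pattern to be explained, found in the same samples, so it is not a separate test. Uneven spread of values between arrays is argued against by the gap after quantile normalization (-69.4, 95% interval -105 to -34.2). A selective difference between the inhibitors remains a candidate explanation for the gap of -64.8 (95% interval -97 to -32.6), found and tested in the same samples. A difference in myeloid cells between these groups was not tested as a source of the gap and stays open. Splits of the 8 samples that kept 2 of each dose on either side gave at most 14 genes beside the real 42, with 1 of 18 splits as high, too few for a share under 0.05. A fit without a term for dose called 0 genes (664 at an unadjusted p under 0.05).

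Myeloid marker genes fell with IL-2, with 8 of 15 macrophage and monocyte markers lower, although the cells were enriched by negative selection. Dilution by RNA of the NK cells would lower the markers of all other cell types alike. The T cell list, which is dim, stood 0.804 above the macrophage and monocyte list in its change (95% interval 0.447 to 1.16), the brighter B cell list 0.358 above (0.223 to 0.493) and the dendritic cell list 0.456 above (0.365 to 0.547). This argues against dilution as the whole cause only if IL-2 induced no member of these lists. Bst2 of the dendritic cell list is also one of the interferon-stimulated genes, which rose with IL-2. The neutrophil list stood at -0.0586 (-0.391 to 0.274), and neutrophil, B cell and dendritic cell markers fell too, so dilution as a part of the fall stays open. Uneven spread between arrays would end the calls, and 8 of the 8 markers were still lower after quantile normalization. A smaller share of monocytes and macrophages in the IL-2 samples may contribute, but 3 of the 7 markers with an untreated log2 mean of at least 7 (Cd68, Mpeg1 and Cybb) had intervals that left out the median fall of -1.73, so a loss of cells alone and a change within them cannot be told apart. Lyz2 and Cybb had the highest untreated log2 means of these (11.76 and 11.25), values that do not rank abundance between genes.

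At 0.0625 µM of the JAK1 inhibitor, in 1 sample, 21 of 24 response lists were lower by limma's camera at the preset correlation and 0 with an estimated correlation. Narrower spread on this array could lower lists of high expression, but 14 of the 21 were still lower after quantile normalization, where the median of the list medians moved from -0.24 to -0.17. A weak effect of the dose and a property of this array are both open, since 1 sample cannot part them.

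Outside the genes analysed, 3497 probe sets without a single gene symbol were tested by the same fit, and 150 differed between IL-2 and untreated cells, 106 higher and 44 lower.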

How the results depend on the processing

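The fits within a scale set, those without a scale-set term, with a title-form term or with a replicate block, and those with genes chosen in 1 scale set, in the forms used here, were chosen after the data had been seen, and the other alternatives before. Of 3460 alternative values for 197 results on named genes, 3091 kept their direction and their side of the threshold, 341 kept only the direction, 15 newly passed and 13 changed sign. With a robust prior 197 of 197 were the same, with every probe set counted as itself 196, with 16 added 194, with dim probe sets left out 188 of the 189 still measured, after quantile normalization 192 of 197, and on leaving out 1 sample 1074 of 1153. Within the high-intensity set, with 1 residual degree of freedom, 11 of 148 were the same and 137 no longer passed. Of 569 alternative values for the other results, 392 were the same. Values that moved or turned follow, and the cause was not tested except where fewer samples were fitted. Response lists called over the planned comparisons fell from 210 to 39 with an estimated correlation. Fits of only the compared groups left 1 residual degree of freedom between the inhibitors at a single dose and for the JAK1 slope. The same held for 4 µM of the JAK1 inhibitor against untreated cells. The counts of fits of only the compared groups and those of the main fit rest on different estimates of the spread. The limit set by background could not be measured.

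Gene counts after quantile normalization were 1685, 2062 and 2498 for 0.25, 1 and 4 µM of the JAK3 inhibitor against IL-2 (987, 1293 and 1483 in the report), 7, 1127, 1728 and 1311 for the JAK1 inhibitor from 0.0625 to 4 µM (4, 445, 1019 and 745), 273 between the inhibitors at 0.25 µM (89), 125 averaged (42) and 911 for the JAK1 slope (549). With only the compared groups fitted they were 2258 and 2582 for 0.25 and 1 µM of the JAK3 inhibitor, 351, 1770, 2092 and 1744 for the JAK1 inhibitor, 1114, 84 and 1 between the inhibitors at 0.25, 1 and 4 µM, 440 averaged, 65 and 1890 for the JAK3 and JAK1 slopes and 78 for 4 µM of the JAK1 inhibitor against untreated cells. Leaving out dim probe sets gave 1 gene at 0.0625 µM, and adding 16 gave 2 there and 347 for the JAK1 slope.

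Within the low-intensity set the counts were 962 for IL-2 (1808 with all samples), 113, 261 and 638 for the JAK3 inhibitor, 9, 53, 257 and 315 for the JAK1 inhibitor, 0 between the inhibitors at 0.25 µM and averaged, and 103 for the JAK1 slope. Within the high-intensity set they were 0 for IL-2, for 0.25 and 1 µM of either inhibitor, between the inhibitors at 0.25 µM and averaged; it held no sample at 0.0625 or 4 µM. Both hold fewer samples. Cish between the inhibitors at 1 µM was -0.065 within the low-intensity set. Without a scale-set term, after quantile normalization, the counts were 1150 for IL-2, 612 and 839 for 0.25 and 1 µM of the JAK3 inhibitor, 2, 152, 615 and 430 for the JAK1 inhibitor, 31 and 9 between the inhibitors at 0.25 µM and averaged, and 4 and 98 for the slopes. With the title-form term on values as deposited, where 1 sample sits on the other scale, they were 269 for IL-2, 90, 169 and 8907 for the JAK3 inhibitor, 0, 25, 134 and 112 for the JAK1 inhibitor, 6 and 6 between the inhibitors, 280 and 26 for the slopes and 2195 for 4 µM of the JAK3 inhibitor against untreated cells. There Jak1 at 4 µM of the JAK3 inhibitor was -0.11, Cish and Jak1 between the inhibitors at 4 µM were 0.47 and 0.49, and the JAK3 slope of Ubxn2a was -0.037. With that term after quantile normalization the counts were 1706, 2136 and 3554 for the JAK3 inhibitor, 15, 1181, 1766 and 1375 for the JAK1 inhibitor, 337 and 137 between the inhibitors, 86 and 894 for the slopes and 39 for 4 µM of the JAK3 inhibitor against untreated cells, and Ifng between the inhibitors at 4 µM was -0.023. The JAK3 slope of Ifng was 0.0026 with the title-form term, without a term and with the replicate block, each after quantile normalization.

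Deviations of 38 same-numbered pairs from their group means correlated at -0.54 to 0.698, with 16 above 0.1. They were taken after removal of the scale-set term. At 0.25 and 1 µM replicate 1 lay in the high- and replicate 2 in the low-intensity set. An effect shared by a replicate number would thus be removed as well. Groups of 2 samples also give the same value for both replicate numbers. These values therefore cannot tell whether replicate numbers pair the samples. A replicate block in place of the scale-set term, after quantile normalization, moved the counts to 1625 and 5685 for 0.25 and 4 µM of the JAK3 inhibitor, 6499, 1886 and 1124 for 0.0625, 1 and 4 µM of the JAK1 inhibitor, 192 between the inhibitors at 0.25 µM, 11 and 890 for the slopes and 4419 for 4 µM of the JAK3 inhibitor against untreated cells. The block on values as deposited, and the fit there without a term, were not run, since they would hold the difference between the scales. Sample weights, which did not converge, were not used.

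On leaving out 1 sample the counts ranged from 1210 to 3069 for IL-2, 309 to 1034, 468 to 1396 and 1000 to 1708 for the JAK3 inhibitor, 2 to 17, 32 to 723, 256 to 997 and 493 to 829 for the JAK1 inhibitor, 5 to 23, 0 to 2 and 0 to 27 between the inhibitors at 0.25, 1 and 4 µM, 17 to 29 averaged, 0 to 171 and 312 to 758 for the JAK3 and JAK1 slopes, and 0 to 49 and 0 to 2 for 4 µM of the JAK3 and JAK1 inhibitor against untreated cells. A group left with 1 sample was assumed to vary like the others. The single samples at 0.0625 and 4 µM of the JAK1 inhibitor could not be left out. Ranges that rest on them, that of the JAK1 slope included, do not show how far the counts depend on these samples. At 4 µM of the JAK3 inhibitor more genes were lower than higher in the full fit, and the reverse held without its replicate 1. Between the inhibitors Cish at 1 µM ranged from -0.026 without replicate 1 of the JAK1 inhibitor to 0.35, and at 4 µM Gzmb from -0.055 to 0.26 and Ifng from -6.3e-04 to 0.22, both lowest without replicate 1 of the JAK3 inhibitor, and Jak1 from -0.26 to 0.029, highest without its replicate 2.

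The percent of induced genes left ranged from 26.5 to 43.0 and 2.17 to 23.7 at 0.25 and 1 µM of the JAK3 inhibitor and from 43.2 to 53.0, 7.85 to 33.0 and -17.4 to 6.06 at 0.25, 1 and 4 µM of the JAK1 inhibitor on leaving out 1 sample. That of repressed genes ranged from -1.72 to 6.17 at 0.25 µM of the JAK3 inhibitor and from -0.63 to 9.32 and 7.7 to 15.4 at 1 and 4 µM of the JAK1 inhibitor. The correlation of repressed genes with JAK3 inhibitor dose ranged from -0.0781 to 0.228. The single sample at 4 µM of the JAK1 inhibitor was never left out, and for the correlation no sample of the JAK3 inhibitor was.

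For the percent of induced genes left at 0.25 µM of the JAK1 inhibitor (48.2), where the 2 samples lay close together, the value was 46.0 and 50.6 with log2 changes of at least 0.5 and 2, 46.8 as a median, 50.8 without a term and 42.8 with genes chosen in the low- and measured in the high-intensity set. With genes chosen that way it was 15.7 and -11.7 at 0.25 and 1 µM of the JAK3 inhibitor (33.6 and 11.0). For the repressed genes that choice gave 8.31 and 3.18 at 0.25 and 1 µM of the JAK3 inhibitor and 12.9 at 1 µM of the JAK1 inhibitor, and the opposite choice gave -8.58 and -22.5, then 38.8, -9.59 and 0.837 at 0.25, 1 and 4 µM of the JAK1 inhibitor. At 0.25 µM of the JAK3 inhibitor (0.206) and 1 µM of the JAK1 inhibitor (1.56) the repressed genes gave -3.19 and -3.03 at a log2 change of at least 0.5, 7.93 and 4.72 at 2, 8.24 and 10.6 without a term, 7.74 and 10.4 after quantile normalization and 7.87 and 11.2 with the replicate block. The correlation of the repressed genes with JAK3 inhibitor dose (0.126) was -0.0122 and -0.506 at log2 changes of at least 0.5 and 2, -0.474 without a term, -0.0767 after quantile normalization and -0.323 with the block. That of the induced genes was -0.695 at a log2 change of at least 0.5 (-0.884 in the report).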

Other observations

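The gene list tests of this part were planned, and none was chosen only after the result was seen.

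IL-2 also changed nutrient and energy genes. Of 27 genes of amino acid transport and ATF4 targets 11 rose and 2 fell (15 and 2 adjusted over the list alone; adjusted p = 0.184 with an estimated correlation, from limma's camera). The tryptophan tRNA ligase gene Wars, also on the interferon-gamma-responsive list, rose (2.53 ± 0.17), as did the transporter gene Slc7a5 (1.86 ± 0.20). The cystine transporter gene Slc7a11 fell (-2.02 ± 0.20). All 3 moved the opposite way with 1 µM of either inhibitor: Wars by -1.93 ± 0.19 and -1.85 ± 0.19 against IL-2 alone with the JAK3 and the JAK1 inhibitor, Slc7a5 by -1.82 ± 0.23 and -1.46 ± 0.23, and Slc7a11 by 2.10 ± 0.23 and 1.67 ± 0.23. Of 25 glycolysis and hypoxia-regulated genes 5 rose and 2 fell (7 and 2 adjusted over the list alone; adjusted p = 0.553 with an estimated correlation), led by the phosphofructokinase gene Pfkp (1.39 ± 0.17), which fell with both inhibitors at 1 µM (-1.33 ± 0.19 and -0.98 ± 0.19, the latter call ending without replicate 2 of that dose at adjusted p = 0.158). The 25 include Pigq, matched through a synonym to the list's entry Gpi1, which is not a gene of glycolysis. Oxidative phosphorylation genes rose in 6 of 30 members (13 adjusted over the list alone; adjusted p = 0.241 with an estimated correlation), with Uqcrq (0.69 ± 0.16) first, whose call ended without untreated replicate 4 (adjusted p = 0.0599). In the sterol and fatty acid synthesis list 2 of 28 rose and 1 fell (3 and 1 adjusted over the list alone; adjusted p = 0.553 with an estimated correlation): Fasn (1.11 ± 0.20) and Lss (0.81 ± 0.17) rose and Scd1 fell (-0.63 ± 0.14).

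Genes of early activation, cytokine receptors and survival changed with IL-2 too. Of 26 immediate early genes 10 rose and 1 fell (11 and 2 adjusted over the list alone; adjusted p = 0.256 with an estimated correlation). The activation marker gene Cd69 (1.88 ± 0.18) and the transcription factor gene Jun (1.38 ± 0.17) rose and Rgs2 fell (-1.18 ± 0.15), and at 1 µM of the JAK3 and the JAK1 inhibitor Cd69 stood at -2.06 ± 0.21 and -1.71 ± 0.21 against IL-2 alone. Of 34 JAK-STAT components 8 rose and 2 fell (9 and 2 adjusted over the list alone; adjusted p = 0.566 with an estimated correlation), led by the receptor genes Il2rb (1.52 ± 0.16) and Il12rb1 (1.69 ± 0.19). The list's median was 0.09, and -0.06 after quantile normalization. Apoptosis regulators rose in 8 of 24 members and fell in 1 (9 and 1 adjusted over the list alone; adjusted p = 0.184 with an estimated correlation), with Bcl2 first and Bcl2l1 next (1.04 ± 0.13). Against IL-2 alone the camera test put this list lower at 0.25 and 1 µM of the JAK3 inhibitor (adjusted p = 0.00714 and adjusted p = 0.0102; adjusted p = 0.209 and adjusted p = 0.235 with an estimated correlation), while its medians were 0.01 and 5.0e-04. NF-kappaB targets had 3 of 20 members higher and 1 lower, with a median of 0.10 that was -0.04 after quantile normalization (adjusted p = 0.499).

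Markers of the remaining cell types moved little with IL-2. For erythroid markers 1 of 11 rose (adjusted p = 0.244, limma's camera), for platelet and megakaryocyte markers 1 of 6 fell (adjusted p = 0.0339, and adjusted p = 0.148 with an estimated correlation), and for stroma and endothelium markers 2 of 11 rose (adjusted p = 0.867). Basophil and mast cell markers (0 of 8; adjusted p = 0.266) and markers of innate lymphoid types 2 and 3 (0 of 7; adjusted p = 0.233) had no member past the test by limma.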
